A study of Rattus norvegicus with 2 samples.

How the data were processed

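The data were 2 two-colour arrays of rat liver total RNA, 1 per sample, of an Agilent rat design with 45018 spots, of which 43379 were for genes and carried 41012 distinct probes. Per the labels, RNA of choline-deficient and control rats was labelled with Cy3 and Cy5, and the channels of each sample name the diet, which gave the direction of every ratio. Per the file headers, the authors extracted the images with Agilent Feature Extraction 9.5.3.1 (9.5 in the submitters' processing notes), and probe coordinates are those of the rat build rn4. The deposited scanner files hold raw spot and background intensity values for each dye. They also hold the authors' deposited log10 ratio of Cy5 over Cy3 processed signal, which per the file headers follows background subtraction with spatial and multiplicative detrending and a lowess dye normalization. Per the file headers, the deposited p-value of each log ratio comes from the error model of Feature Extraction within 1 array. The series table of deposited values equalled the log10 ratio of each array row by row within 1% of each value (45018 of 45018 rows on both arrays), with a median of 0 in each column, scale log10, direction Cy5 over Cy3 and no turning for the dye swap. Its row numbers equalled the feature numbers of the scanner files in only 2930 rows, so no probe was named from it and it was not run as a separate alternative.

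Signals were background-corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50 on mean signal and median local background, and log2 ratios were normalized by loess within each array with control spots at weight 0. The offset draws ratios of dim spots towards 0, so folds of weakly expressed genes are understated. Spots flagged as outliers (174 and 151 spots) were left out, and spots of a probe were averaged (263 probes had 10 spots). The SD of the log2 ratio among the 10 spots of a probe on an array had a median of 0.0617 on array 1 and 0.0520 on array 2 over 166 kept probes, which gives the precision within an array. The median Cy3 and Cy5 mean signals were 119 and 135 on array 1 and 136 and 155 on array 2, against a median background of 47 in Cy3 and 46 in Cy5 on both. A probe was kept where it was well above background on both arrays for at least one diet (22364 probes), and each gene was represented by its probe of highest mean intensity, leaving 18195 genes. Of 363 called genes with several kept probes, 31 had a probe whose mean had the opposite sign. For a gene well above background on neither array in one diet, the fold is a bound, from the mean normalized log2 level in the brighter diet against, per array, the higher of the lowest level among detected probes and the probe's own (per channel, after loess and A-quantile scaling).

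Array 1 and array 2 were turned to choline-deficient over control and tested against 0 with limma's lmFit and eBayes, two-sided, with 1 residual degree of freedom per gene, a prior of 63.0 degrees of freedom and Benjamini-Hochberg adjustment over all genes tested. A dye effect cancels in the mean of the swapped arrays and counts as spread. SDs are over the 2 arrays. For the reading in which both arrays held the same extracts, genes of at least 2-fold in the same direction on each array were counted without a test. The 30 gene lists were tested with camera with a preset correlation of 0.01 and again with an estimated one. The lists and their tests, the rule for named genes and the alternatives were fixed before the data were examined, except the alternatives with an intensity trend on the deposited log ratio and without the brightest genes, and the gene groups and tests of the closing section. The rule takes the 12 highest and 12 lowest mean log2 ratios among genes past the adjusted p of 0.05 with a log2 ratio of at least 1 on both arrays in that direction, up to 4 members of each list with the largest absolute mean log2 ratio, and any member of the first 2 lists, and passes over names that are accessions or LOC and RGD numbers (6999 of the genes tested). Genes outside it (Ambp, Hp, Cyp7a1, Cd68, Csf1r, Col1a1, Cxcl2, Krt18, Krt19, Tat, and those of the closing section) were chosen after their values were seen. A few genes that the rule takes are not reported here. Gene names are those of the array files. Through unversioned RefSeq accessions, 9518 of the tested genes matched the table of assembly GRCr8, used for names only, and 960 of these have another current symbol.

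The procedure was tested on simulated data made from the deviations between the arrays, with 200 genes changed and a list of 47 further genes shifted among 18195. At 1.3-fold, 50% of 50 changed genes were called in the right direction, at 1.5-fold 98%, and at 2-fold and 3-fold 100%, with 17 of 17948 unchanged genes called. With no effect simulated, 0 genes were called. The deviations were drawn for each gene on its own, so the simulated data held no correlation between genes. They also held no spread between rats beyond what the arrays show, so these false calls do not cover such spread. Alternatives covered the background correction, the normalization, the dim-probe filter, the choice of probe, eBayes settings, Feature Extraction's own p-value, fold thresholds, camera settings and leaving out each array. Both arrays lie on the same slide, so no batch could be compared. Spike-in and negative control spots took no part in the tests.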

Results

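Liver RNA of rats fed a choline-deficient diet was compared with liver RNA of rats on a control diet after 10 days, in Wistar rats of 7 weeks (the strain is spelled Wister in the labels). Choline is needed to make phosphatidylcholine and, through betaine, to remethylate homocysteine to methionine. Total RNA was hybridised to 2 two-colour oligonucleotide arrays, with the choline-deficient RNA in Cy5 on array 1 and in Cy3 on array 2, so that the dyes were swapped. The labels speak of 4 choline-deficient rats and do not say whether the arrays held RNA of different rats or the same pair of extracts. The p-values therefore measure only the spread between these 2 arrays, which may be technical. That spread is largely pooled over genes (63.0 prior against 1 residual degree of freedom), so a gene's own spread counts for little. Of 43379 spots for genes on each array, 54.2% in Cy3 and 62.9% in Cy5 were well above background on array 1, and 53.5% and 63.2% on array 2. No spot was saturated. Across the 18195 genes tested, log2 ratios turned to choline-deficient over control correlated between the arrays (Pearson r = 0.55 and Spearman rho = 0.30 across genes, which are not independent replicates). The number of arrays limits the precision of all values.

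The comparison asked which hepatic genes responded to the choline-deficient diet. More genes rose than fell among cholesterol (15 of 23 rose), cell cycle (24 of 32) and inflammatory genes (9 of 27). More fell than rose among bile acid (6 of 19 fell), drug metabolism (10 of 29) and sex-biased genes (10 of 22). As groups, none of the 30 gene lists tested was called when the correlation between genes was estimated. With 1 residual degree of freedom, that test could hardly call any list. In limma's test, 795 genes were higher and 773 lower in choline-deficient liver at a Benjamini-Hochberg adjusted p under 0.05. Of these 1568 genes, 1562 had the same direction on both arrays, against 56.4% of all genes tested. The test itself favours such agreement, since it was run on the same arrays. Most changes were small, since 193 of the higher and 145 of the lower genes reached 1.5-fold on average. At least 2-fold on each array, 35 genes were higher and 18 lower, a count by size with no test. With the deposited log ratio in place of the offset-corrected signals, limma called 0 genes (2122 at an unadjusted p under 0.05) while 112 genes were higher and 44 lower by at least 2-fold on both arrays. With median centring in place of loess, it called 0 genes (19 at an unadjusted p under 0.05), with 11 higher and 1 lower by at least 2-fold on both arrays.

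**Figure D1:**
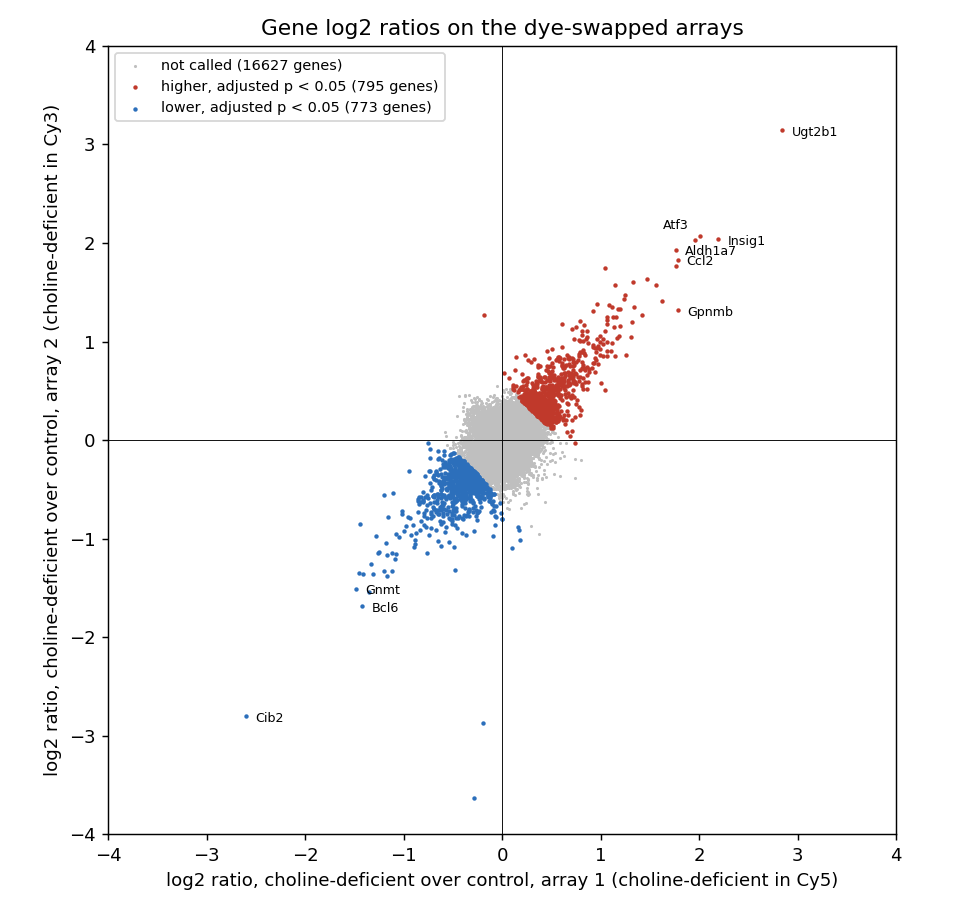
Log2 ratio of choline-deficient over control liver on array 1 (x axis) and array 2 (y axis), each point 1 of 18195 genes, with the 795 genes called higher in red and the 773 called lower in blue. Ugt2b1 (2.84 and 3.14) and Cib2 (-2.59 and -2.80) lie apart from all other genes along the diagonal.

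Genes are ranked here among those that carry a symbol, passed limma's test and changed at least 2-fold on both arrays. The most increased of these was Ugt2b1, a glucuronosyltransferase, whose log2 ratio was 2.99 ± 0.21 (SD, n = 2 arrays), or 7.97-fold (limma adjusted p = 2.26e-34). Its probe lies on chromosome 14 from 22650838 to 22650897 in the rat build rn4 that the array files use. Insig1, a sterol-responsive regulator of the SREBP pathway, rose 4.33-fold (2.11 ± 0.11, adjusted p = 2.06e-26) at a probe on chromosome 4 from 2577508 to 2577567, and its other kept probes were higher too, by up to 1.96 on the log2 scale. The stress-induced transcription factor Atf3 rose 4.11-fold (2.04 ± 0.04, adjusted p = 9.53e-26) and the monocyte chemoattractant Ccl2 rose 3.50-fold (1.81 ± 0.03, adjusted p = 3.96e-23). Aldh1a7, Btg2, Ubd, Gpnmb, Spp1, H19, Ect2 and Gstm3 completed the 12 most increased of these genes, with log2 ratios from 1.85 for Aldh1a7 to 1.36 for Gstm3. The most decreased of them was Cib2, which encodes a calcium- and integrin-binding protein and was 6.50-fold lower (-2.70 ± 0.15, adjusted p = 3.10e-32) at a probe on chromosome 8 from 58095063 to 58095122. Bcl6, a transcriptional repressor, was 2.93-fold lower (-1.55 ± 0.19), although a second, dimmer probe for it gave -0.26. Gnmt, the glycine N-methyltransferase that consumes S-adenosylmethionine, was 2.82-fold lower (-1.50 ± 0.02, adjusted p = 3.41e-19) at a probe on chromosome 9 from 10130178 to 10130237. Lox, the bile acid CoA ligase gene Slc27a5, the alcohol dehydrogenase Adh1 (now Adh1c), Aspg, Slc16a11, Nim1 (now Nim1k), Car3, Spink3 and Gadl1 completed the 12 most decreased of these genes, from -1.40 for Lox to -1.15 for Gadl1. Lox also had a dimmer probe at -0.63. Probes for members of multigene families (Ugt2b, Cyp2c, Cyp3a, Gstm and Sult genes) can bind paralogs, which was not searched here.

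Of 30 gene lists fixed before the data were examined, limma's camera with a preset correlation of 0.01 called 9 higher and 8 lower. With an estimated correlation, which rests on 1 residual degree of freedom, camera called 0 of the 30 lists and none had an unadjusted p under 0.05 (the smallest adjusted p was 0.418). At 1 degree of freedom this test could hardly call any list, so its lack of calls does not count against a list. The preset correlation in turn was assumed and not measured here. Counts below are over all genes tested unless they are said to be adjusted over the list alone.

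**Figure D2:**
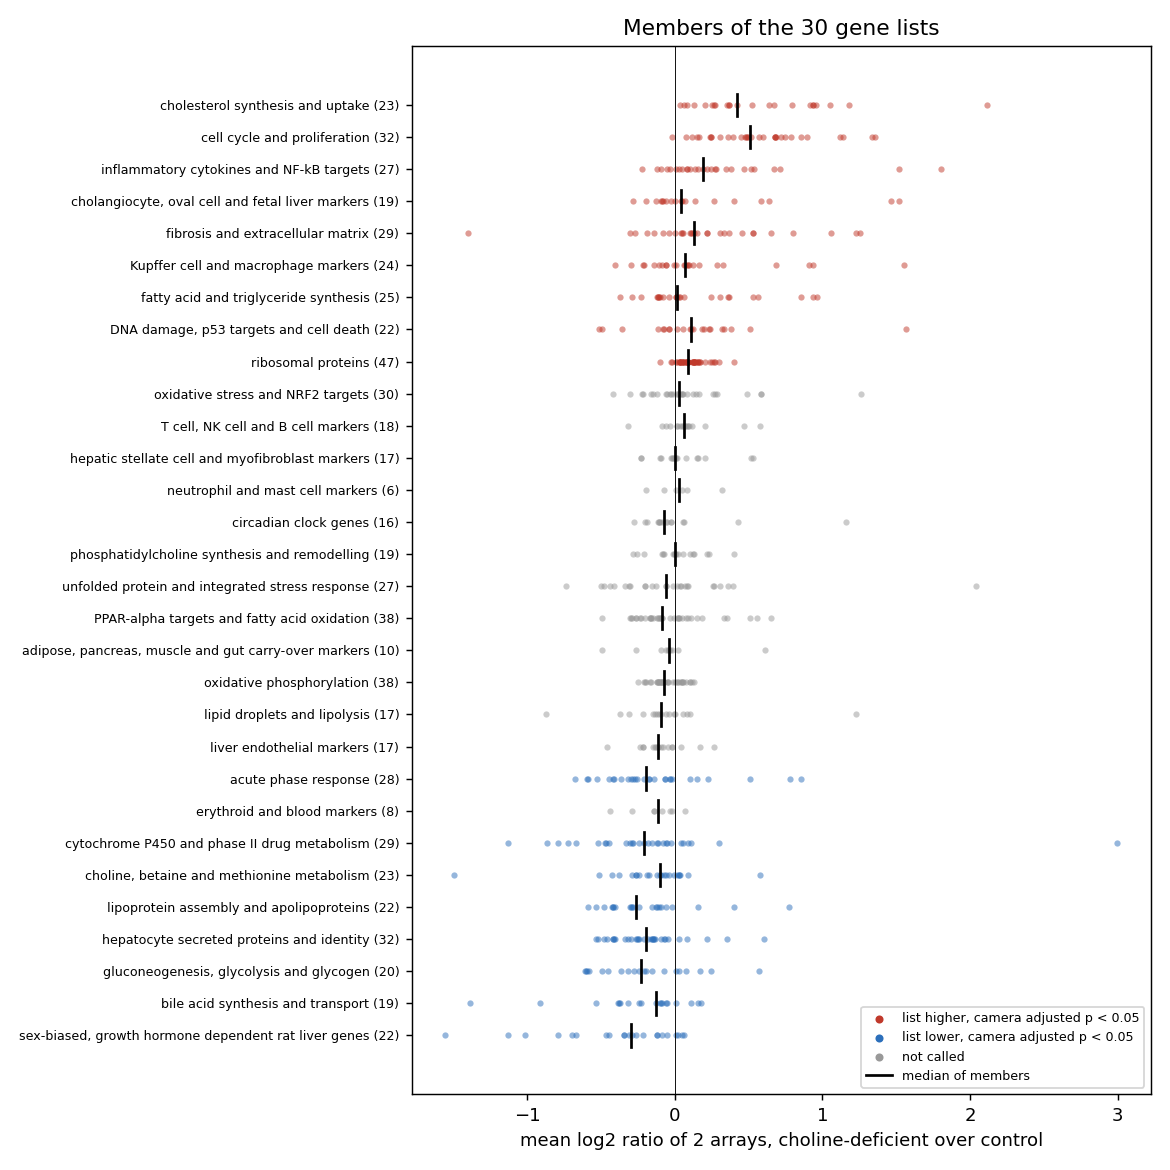
Mean log2 ratio of both arrays for each tested member (points) of the 30 gene lists (rows, with the number of members), with the median as a black bar and colour by camera's call with the preset correlation. Of the cell cycle genes (median 0.51) 31 of 32 lie above 0 on both arrays, and of the cholesterol genes (median 0.42) 21 of 23. No list is called with an estimated correlation.

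Genes of the choline, betaine and methionine list were lower as a group (camera adjusted p = 0.000545, adjusted p = 0.418 with an estimated correlation). Of 23 members, 1 rose, 4 fell and 18 did not pass; adjusted over the list alone, 1 rose and 8 fell. Beside Gnmt, the genes that fell were the betaine-homocysteine methyltransferase Bhmt (-0.51 ± 0.16, SD, n = 2 arrays), Gamt (-0.43 ± 0.09) and the liver form of methionine adenosyltransferase, Mat1a (-0.37 ± 0.17). Mat2a, the form that predominates outside the adult liver but was well above background in control liver on both arrays, rose (0.58 ± 0.07). The choline oxidation enzyme Chdh (-0.04 ± 0.19) and the cystathionine synthase Cbs (-0.24 ± 0.05) did not pass. In the phosphatidylcholine synthesis list, the choline kinase Chka rose (0.40 ± 0.00, adjusted p = 0.00379), and the remaining 18 of 19 members did not pass, with the count the same when adjusted over the list alone. Pcyt1a, the rate-limiting enzyme of the CDP-choline route, was at 0.22 ± 0.14, and Pemt, which methylates phosphatidylethanolamine, was at -0.26 ± 0.31. The list was not called (adjusted p = 0.815).

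Cholesterol synthesis and uptake genes were higher (median 0.42, camera adjusted p = 4.18e-30, adjusted p = 0.418 with an estimated correlation), and 15 of 23 rose with none lower, or 18 adjusted over the list alone. After Insig1, the largest changes were in the squalene epoxidase Sqle (1.18 ± 0.03), Cyp51 (1.05 ± 0.09) and Fdps (0.96 ± 0.04). Of 25 fatty acid and triglyceride synthesis genes, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone. The fatty acid synthase Fasn rose by 0.96 ± 0.21, the desaturases Fads2 and Fads1 by 0.93 ± 0.01 and 0.86 ± 0.11, and Pnpla3, not well above background in control liver, by at least 1.43-fold. This list's median was 0.02 (0.03 on array 1 and 0.06 on array 2; camera adjusted p = 0.00418, adjusted p = 0.418 with an estimated correlation), and the call was lost with the deposited log ratio (adjusted p = 0.0674) and on ranks (0.369). Of 17 lipid droplet genes, the fatty acid-binding protein Fabp4, well above background in control liver on 1 of the arrays, rose (1.23 ± 0.21), and Cidec (-0.87 ± 0.06), Fitm2 (-0.37 ± 0.24) and Hsd17b11 (-0.31 ± 0.18) fell, with the same counts adjusted over the list alone and no call for the list (adjusted p = 0.162). Of 38 PPAR-alpha targets and fatty acid oxidation genes, 5 rose and 2 fell, or 5 and 6 adjusted over the list alone. Acot1 (0.65 ± 0.09), Fabp1 (0.55 ± 0.35) and Acaa1b (0.51 ± 0.11) rose and Angptl4 (-0.49 ± 0.03) fell, and the list was not called (adjusted p = 0.393).

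Apolipoprotein and lipoprotein assembly genes were lower (median -0.26, but -0.09 on array 1 and -0.18 on array 2 alone, camera adjusted p = 5.41e-05, adjusted p = 0.418 with an estimated correlation), with 2 of 22 higher and 7 lower, or 2 and 12 adjusted over the list alone. Apob, the structural protein of very low density lipoprotein, fell (-0.59 ± 0.05), as did Apoc1 (-0.54 ± 0.27), while Apoa2 rose (0.78 ± 0.38). Of 19 bile acid genes, 6 fell and none rose, or 8 fell adjusted over the list alone (camera adjusted p = 2.84e-06, adjusted p = 0.418 with an estimated correlation). Slc27a5 fell by 1.39 on the log2 scale (SD 0.04), the bile acid uptake transporter Slc10a1 changed by -0.91 ± 0.05 and Slco1b2 by -0.53 ± 0.16, and the rate-limiting synthetic enzyme Cyp7a1 was at 0.15 ± 0.08 without passing. Of 29 cytochrome P450 and phase II genes, 2 rose and 10 fell, or 2 and 14 adjusted over the list alone (camera adjusted p = 5.57e-07, adjusted p = 0.418 with an estimated correlation). Sult2a1 (-1.13 ± 0.21), Cyp1a2 (-0.87 ± 0.21) and Cyp3a2 (-0.79 ± 0.42) fell, against the rise of Ugt2b1. Of 22 sex-biased, growth hormone-dependent genes, 10 fell and none rose, or 13 fell adjusted over the list alone (camera adjusted p = 5.57e-15, adjusted p = 0.418 with an estimated correlation). They held Bcl6, Sult2a1 and Cyp2c12 (-1.01 ± 0.08), and 6 of the 22 members were also in other lists. Of 20 gluconeogenesis, glycolysis and glycogen genes, 1 rose and 8 fell, or 2 and 10 adjusted over the list alone (camera adjusted p = 2.87e-05, adjusted p = 0.418 with an estimated correlation). The glycogen synthase Gys2 (-0.61 ± 0.15), Fbp1 (-0.60 ± 0.28) and Pc (-0.59 ± 0.16) fell, and Tat, an aminotransferase, rose (0.57 ± 0.13).

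**Figure D3:**
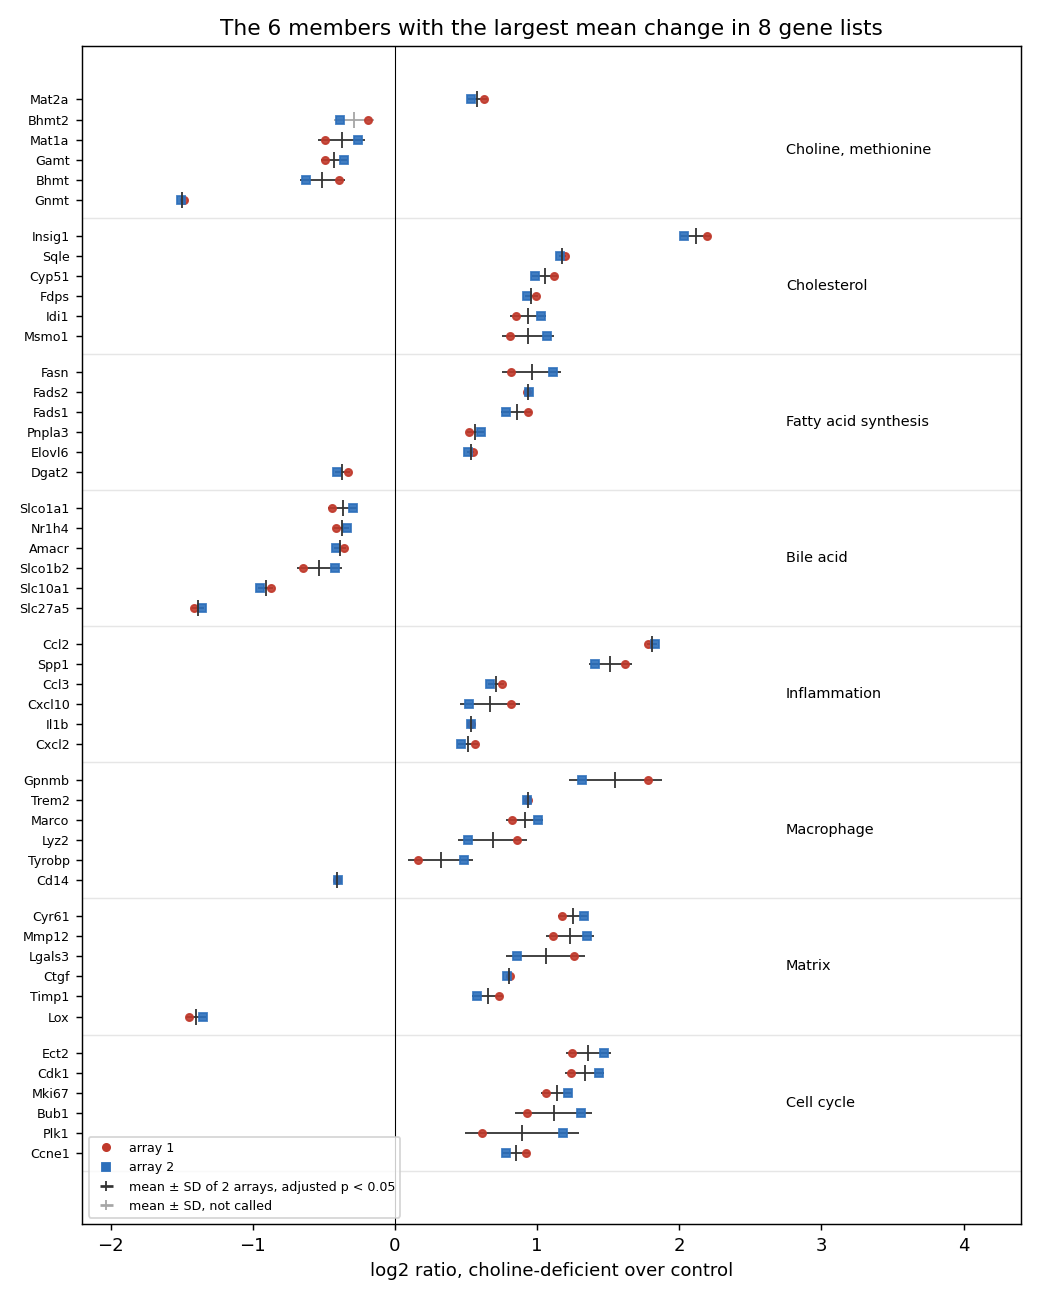
Log2 ratio of choline-deficient over control liver (x axis) on array 1 (red circles) and array 2 (blue squares) for the 6 members with the largest mean change in 8 of the gene lists, with the mean and its SD over 2 arrays in black where limma's adjusted p was under 0.05 and in grey otherwise. Gnmt (-1.49 and -1.51) and Ccl2 (1.78 and 1.83) had nearly equal values on both arrays, while Gpnmb had 1.78 and 1.32.

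Inflammatory cytokine genes and NF-kB targets were higher (median 0.19, camera adjusted p = 7.64e-10, adjusted p = 0.418 with an estimated correlation). Of 27 members, 9 rose and none fell, or 12 rose adjusted over the list alone. Spp1, which encodes osteopontin, rose by 1.52 ± 0.15 (SD, n = 2 arrays), the chemokines Ccl3 and Cxcl10 by 0.71 ± 0.06 and 0.67 ± 0.21, and Cxcl2, not well above background in control liver, by at least 1.43-fold. Of 29 fibrosis and extracellular matrix genes, 11 rose and 1 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 2.84e-06, adjusted p = 0.418 with an estimated correlation). The matricellular gene Cyr61 (1.25 ± 0.11), the macrophage elastase Mmp12 (1.23 ± 0.17) and Lgals3 (1.06 ± 0.28) rose, as did the collagen Col1a1 (0.53 ± 0.02), and Lox, which cross-links collagen, fell. Of 24 Kupffer cell and macrophage markers, 5 rose and 1 fell, or 6 and 2 adjusted over the list alone, with a median of 0.07 (0.09 on array 1 and 0.02 on array 2; camera adjusted p = 0.00805, adjusted p = 0.454 with an estimated correlation). Gpnmb (1.55 ± 0.33), Trem2 (0.93 ± 0.01), Marco (0.91 ± 0.13) and Lyz2 (0.69 ± 0.24) rose. The widely used macrophage markers Cd68 (0.16 ± 0.14) and Csf1r (0.12 ± 0.00) did not pass, and the list's call was lost with the deposited log ratio (adjusted p = 0.0878) and on ranks (0.335). Of 19 cholangiocyte, oval cell and fetal liver markers, 5 rose and none fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.000759, adjusted p = 0.418 with an estimated correlation). These were Spp1, the imprinted fetal transcript H19 (1.46 ± 0.19), Krt8 (0.64 ± 0.01), Anxa2 (0.58 ± 0.20) and Krt18 (0.40 ± 0.33), which other cells also express, while the cholangiocyte keratin Krt19 was at -0.02 ± 0.11. The list's median was 0.04 (-0.01 on array 1 and 0.08 on array 2) against a mean of 0.22, and the call was lost on ranks (adjusted p = 0.335).

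Markers of the remaining cell types were not called as lists. Liver endothelial markers had a median of -0.11 and 1 of 17 fell, Kdr at -0.46 ± 0.17 (adjusted p = 0.0727 for the list). Of 17 stellate cell and myofibroblast markers, Vim (0.53 ± 0.06) and Tagln (0.51 ± 0.18) rose with a list median of 0.00 (adjusted p = 0.371). Of 18 T, NK and B cell markers, the class II genes Cd74 (0.58 ± 0.15) and RT1-Da (0.47 ± 0.10) rose and Gzma fell (-0.32 ± 0.05), with an adjusted p of 0.154 for the list. Of 6 neutrophil and mast cell markers, S100a8 rose (0.32 ± 0.16; list adjusted p = 0.774). Of 8 erythroid and blood markers, Hbb-b1 fell (-0.44 ± 0.13; list adjusted p = 0.0624). Of 10 adipose, pancreas, muscle and gut markers, Fabp2 rose (0.61 ± 0.01) and Cfd fell (-0.49 ± 0.03; list adjusted p = 0.465). Adjusted over the list alone, the counts were the same for the first 4 of these lists, 2 lower for the erythroid list, and 1 higher and 2 lower for the carry-over list. The call of the endothelial and erythroid lists depended on the processing: both passed without the filter on dim probes (adjusted p = 0.009997 for each).

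Cell cycle genes had the smallest p of the lists in camera with the preset correlation (median 0.51, adjusted p = 3.90e-39, adjusted p = 0.418 with an estimated correlation). Of 32 members, 24 rose and none fell, or 27 rose adjusted over the list alone. Ect2 (1.36 ± 0.16), the mitotic kinase Cdk1 (1.34 ± 0.14), the proliferation marker Mki67 (1.14 ± 0.11) and the spindle checkpoint kinase Bub1 (1.12 ± 0.27) led the list. Of 22 DNA damage, p53 target and cell death genes, 5 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0448, adjusted p = 0.454 with an estimated correlation). Btg2, an antiproliferative gene (1.57 ± 0.01), and Ccng1 (0.51 ± 0.20) rose, Gadd45g (-0.51 ± 0.11) and Gadd45a (-0.49 ± 0.13) fell, and the call was lost with an offset of 16 (adjusted p = 0.0576), with the deposited log ratio (0.0608) and on ranks (0.113). Of 27 unfolded protein and integrated stress response genes, 4 rose and 7 fell, or 6 and 8 adjusted over the list alone (list adjusted p = 0.371). Atf3 rose while Chac1 (-0.74 ± 0.02) and Pdia4 (-0.48 ± 0.14) fell, and Atf5 (-0.50 ± 0.84) differed in sign between the arrays. Of 30 oxidative stress and NRF2 target genes, 4 rose and 2 fell, or 7 and 2 adjusted over the list alone (list adjusted p = 0.0752). Akr7a3 (1.26 ± 0.09), Ephx1 (0.59 ± 0.05) and Gstm1 (0.58 ± 0.10) rose. Of 16 circadian clock genes, Bhlhe41 (1.16 ± 0.13) and Per2 (0.43 ± 0.03) rose, or 2 higher and 1 lower adjusted over the list alone (list adjusted p = 0.99). The median of that list was -0.07 and its mean 0.02, so that they differed in sign.

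Among the most abundant liver transcripts, hepatocyte secreted protein and identity genes were lower (median -0.20, camera adjusted p = 3.29e-06, adjusted p = 0.418 with an estimated correlation), with 2 of 32 higher and 10 lower, or 2 and 14 adjusted over the list alone. The prothrombin gene F2 (-0.53 ± 0.39), Vtn (-0.52 ± 0.36) and Foxa2 (-0.48 ± 0.03) fell and Onecut1 (0.60 ± 0.14) rose, and Ambp, among those lower on average, had opposite signs on the arrays (0.18 and -1.01). Of 28 acute phase genes, 3 rose and 9 fell, or 4 and 13 adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.454 with an estimated correlation). Fgb (-0.67 ± 0.31) and Saa4 (-0.60 ± 0.27) fell, while Il1rn (0.85 ± 0.04) and Cebpd (0.78 ± 0.09) rose, and Hp, among those lower on average, had opposite signs on the arrays (0.16 and -0.88). Ribosomal protein genes were called higher with a median of 0.09 (camera adjusted p = 0.00202, adjusted p = 0.589 with an estimated correlation), with 1 of 47 higher, Rpl32 at 0.40 ± 0.43, also adjusted over the list alone. Their median was 0.20 on array 1 and -0.01 on array 2. Of 38 oxidative phosphorylation genes, 0 passed in limma's test, also adjusted over the list alone, and 3 had an unadjusted p under 0.05 (list adjusted p = 0.162). The arrays differed for very bright genes: 298 genes with a mean log2 intensity over 15 had medians of 0.04 on array 1 and -0.15 on array 2, and without them the acute phase list was no longer called (adjusted p = 0.318, in the opposite direction), nor was the ribosomal list (0.0519).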

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

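Spike-in control spots, which took no part in the comparisons, were well above background more often than negative control spots in Cy5. On array 1 this held for 8 of 320 spike-in spots against 0 of 153 negative spots (one-sided Fisher's exact p = 0.0426), and on array 2 for 18 of 320 against 1 of 153 (Fisher's exact p = 0.0053). In Cy3 the numbers were 2 and 3 of 320 spike-in spots (Fisher's exact p = 0.457 and 0.61). Fisher's test took spots as independent, whether or not they repeat a probe, and these p-values were not adjusted for the number of tests. In both dyes most spike-in spots were not well above background.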

How the results depend on the processing

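The alternatives with an intensity trend on the deposited log ratio, and those without the 298 brightest genes, were chosen after seeing the data, and all others before. Counts of 795 higher and 773 lower genes stayed within 1.5 times with no background correction, an offset of 16, both other dim-probe filters, the mean of all probes, eBayes with a trend or robust, and without the brightest genes. With the deposited log ratio limma called 0 higher and 0 lower genes (2122 at an unadjusted p under 0.05, smallest adjusted p 0.193), although its log2 ratios correlated with those reported (r = 0.89 across genes). There the median SD between arrays rose from 0.0964 in the brightest eighth of genes to 0.402 in the dimmest. It was 0.108 in both with the offset. The prior fell to 2.43 degrees of freedom. With a trend in eBayes the same values gave 1146 higher and 1215 lower genes, of which 1537 were shared with the reported calls. The prior of that fit was infinite, so no gene's own spread counted in its calls. The same held for the trend on the reported values, and without the brightest genes the prior was 570 degrees of freedom. With median centring limma called 0 higher and 0 lower (19 at an unadjusted p under 0.05), as the dye effect that loess removes stayed in (medians 0.65 on array 1 and -0.41 on array 2). Feature Extraction's p under 0.01 on both arrays gave 298 higher and 218 lower genes, and a minimum of 1.5-fold beside the adjusted p gave 193 and 145. Genes of at least 2-fold on both arrays (35 and 18) became 112 and 44 with the deposited log ratio, 11 and 1 with median centring, 155 and 90 at 1.5-fold and 7 and 1 at 3-fold. With 1 array left there is no test: leaving out replicate 1 gave 54 higher and 31 lower genes of at least 2-fold and leaving out replicate 2 gave 46 and 27. Both settings loosen the rule, since 1 array has to pass. No separate paired analysis was run, because each array holds both diets and the ratio tested is already a comparison within the array. Leaving out saturated probes moved nothing, as none was saturated. The series table equals the deposited log ratio and was not run apart.

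Of the 17 called lists, 11 kept their call and direction under all settings but the estimated correlation, under which 0 higher and 0 lower lists were called. The adjusted p was then 0.418 for choline and methionine, fatty acid synthesis, cholesterol, lipoprotein, bile acid, P450, sex-biased, gluconeogenesis, inflammation, fibrosis, cholangiocyte, cell cycle and hepatocyte lists, 0.454 for acute phase, macrophage and p53 lists and 0.589 for the ribosomal list. On ranks, 5 lists were called higher, and the adjusted p was 0.369 for fatty acid synthesis, 0.335 for macrophage and cholangiocyte lists, 0.113 for p53 and 0.0199 for endothelial markers. With the deposited log ratio it was 0.0674 for fatty acid synthesis, 0.0878 for macrophages, 0.0608 for p53, 0.0184 for endothelial and 0.0376 for erythroid markers. An offset of 16 gave 0.0576 for p53. Median centring gave 0.155 for acute phase, 0.00777 for NRF2 targets and 0.0425 for erythroid markers, and turned the direction of uncalled lists (0.522 for PPAR-alpha and unfolded protein response, 0.856 for neutrophil, 0.791 for clock and 0.798 for oxidative phosphorylation genes). Without the dim-probe filter the values were 0.0287 for NRF2 targets and 0.009997 for endothelial and erythroid markers, with all 4 channels above background 0.00685 for lipid droplets, and with the mean of all probes 0.0398 for endothelial and 0.0476 for erythroid markers and 0.88 for clock genes in the other direction. Without the brightest genes it was 0.00944 for NRF2 targets, 0.0519 for ribosomal genes, and 0.318 for acute phase and 0.848 for clock genes, both in the other direction. Among called lists, medians changed sign for cholangiocyte markers (-0.00241 with no background correction, from -0.0071 to 0.0822 with 1 array left out) and ribosomal genes (from -0.0064 to 0.204 with 1 array left out). Beyond sign, medians of called lists moved by over 1.5 times with median centring (choline and methionine -0.000863, fatty acid synthesis 0.188, lipoprotein -0.0961, bile acid -0.00276, P450 -0.0459, sex-biased -0.122, gluconeogenesis -0.0805, acute phase -0.034, fibrosis 0.295, macrophage 0.178, cholangiocyte 0.0701, hepatocyte -0.0602 and ribosomal genes 0.261), with the deposited log ratio (cell cycle 1.04, choline and methionine -0.174, fatty acid synthesis 0.0265 and cholangiocyte 0.0264), without the dim-probe filter (inflammation 0.0939 and cholangiocyte 0.0219), and for fatty acid synthesis with an offset of 16 (0.0321) and the mean of all probes (0.0313). With 1 array left out, medians also moved by over 1.5 times for acute phase (from -0.315 to -0.0549) and fibrosis genes (0.0842 on array 1). Those of the lipoprotein, fatty acid synthesis and macrophage lists on single arrays are given with the lists. Of 125 called genes named in the text, all were in the same direction under each planned setting with both arrays except Rtn4rl1, which was at 0.0161 with all 4 channels above background, where another probe stood for it. With 1 array left out, Ambp ranged from -1.01 to 0.178, Atf5 from -1.1 to 0.0965, Hp from -0.883 to 0.159 and Klf10 from -0.183 to 1.27. Of the named genes that did not pass, A1bg changed sign with the deposited log ratio (-0.0638, also with a trend in eBayes) and with no background correction (-0.0192), and Cyp2a1 with median centring (0.122), and with 1 array left out A1bg ranged from -0.0513 to 0.147, Chdh from -0.17 to 0.0933, Cux2 from -0.0199 to 0.148, Krt19 from -0.103 to 0.0548 and Tf from -0.956 to 0.369. Where no cause is given, the cause was not tested. Signal over background limits dim genes most, since between 53.5% and 63.2% of spots per dye and array were well above background.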

Other observations

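The gene groups in this part were put together, and all its tests chosen, after the results were seen, so the counts of segregation, replication, stress, heat shock and amino acid genes describe and do not test. Genes of chromosome segregation and DNA replication outside the cell cycle list moved with it. Of 14 tested kinetochore and chromosome segregation genes 12 rose and none fell (median 0.74), such as Aspm (1.14 ± 0.00, SD, n = 2 arrays) and Cenpw (0.95 ± 0.03), and of 21 replication and repair genes 16 rose and none fell (median 0.51), such as the chromatin assembly gene Chaf1b (1.07 ± 0.04). Of 25 immediate early and stress response genes, 11 rose and 2 fell, with Klf10, among those higher on average, at opposite signs on the arrays (-0.18 and 1.27): Klf6 (1.19 ± 0.09) and the AP-1 subunits Jun (1.18 ± 0.18) and Jund (0.88 ± 0.21) rose with Atf3, Btg2 and Cyr61, while Ier2 (-0.36 ± 0.07) and Dusp6 (-0.49 ± 0.26) fell and Fosb (-0.09 ± 0.01) and Junb (0.13 ± 0.17) did not pass. Among 10 heat shock genes Hspa1b (1.35 ± 0.01) and Hsp90aa1 (0.44 ± 0.26) rose, and 8 did not pass, among them Hspa1a (0.17 ± 0.11). Of 32 amino acid catabolism genes 13 fell and 1 rose, with Aspg, Gadl1, the ornithine aminotransferase Oat (-1.13 ± 0.02) and the cysteine dioxygenase Cdo1 (-0.71 ± 0.19) among the lowest.

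Large changes were also seen at probes without a gene symbol, which the naming rule passed over: 6 such names were at least 2-fold higher and 5 at least 2-fold lower on both arrays. A probe that the files describe as Cyp2c24 was at 1.99 ± 0.05 and a probe described as similar to an H3 histone at 1.76 ± 0.00. Probes described as endogenous retrovirus sequences were lower, at -1.28 ± 0.15 and -1.21 ± 0.18, while another probe of that description was at 0.20 ± 0.07, and probes for a viral envelope glycoprotein (-1.44 ± 0.13) and a VL30 element (-1.11 ± 0.09) were lower as well. Rtn4rl1 (-0.28 on array 1 and -3.63 on array 2) and Lamtor3 (-0.20 and -2.88) passed limma's test with values that came almost entirely from array 2.

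In the macrophage list, which was not called with an estimated correlation (adjusted p = 0.454), Gpnmb, Trem2, Marco, Lyz2 and Tyrobp rose and Cd14 (-0.41 ± 0.01) fell. A lower share of hepatocyte RNA would raise the markers of other cell types alike. Log2 ratios across the marker lists of 6 other cell types did not decide this (Kruskal-Wallis test by 10000 permutations, p = 0.0659 over 99 genes, taken as independent). Their overall median was 0.0121 (95% bootstrap interval -0.0213 to 0.0635), and list medians ran from -0.103 for endothelial to 0.0708 for macrophage markers. The 6 lists included the macrophage list itself, and the cholangiocyte list holds fetal transcripts and keratins that other cells also express. The interval of endothelial markers (-0.131 to -0.0213) was wholly negative, against a rise of these markers. That of T, NK and B cell markers (0.0126 to 0.0928) was wholly positive, and the intervals of the remaining lists spanned both signs. Of 15 tested genes of a lipid-associated macrophage group, some also in the macrophage list, 11 rose, none fell and 4 did not pass (median 0.69). That count describes and does not test. A larger number of macrophages, a change of their state or mix and a lower share of hepatocyte RNA are candidate explanations that stay open.

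The hepatocyte secreted protein list was lower with the preset correlation and not called with an estimated one (adjusted p = 0.418), with SDs over the arrays as large as 0.94 for Tf and 0.84 for Ambp. The median log2 ratio of the list, -0.197, lay below the central 95% of 10000 random lists matched on intensity (-0.109 to 0.0798). The list was thus lower than other genes of like intensity, with genes drawn as independent. Whether all genes of that intensity shared a shift could not be tested this way. Loess by intensity had already brought the typical ratio at each intensity close to no change. The 104 genes with a mean log2 intensity over 16 had medians of 0.16 on array 1 and -0.33 on array 2. With the dyes swapped, both lay towards Cy5, as a dye effect left in the brightest genes would. What set the arrays apart for single genes was not resolved. Markers of 6 other cell types, which a lower share of hepatocyte RNA would raise, showed no rise as a set (median 0.0121, 95% bootstrap interval -0.0213 to 0.0635). How large a rise would go with the fall of this list depends on the hepatocyte share, which was not measured. A lower output of these transcripts under the diet and a lower share of hepatocyte RNA stay open, and the 2 arrays do not separate them from differences between the rats used.

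The sex-biased list was lower with the preset correlation and not called with an estimated one (adjusted p = 0.418). A shift from the male to the female pattern would raise female-biased genes. Of 7 tested, none rose and 4 fell: Cyp2c12 (-1.01 ± 0.08), Cyp2c7 (-0.47 ± 0.03), Sult2a1 (-1.13 ± 0.21) and Srd5a1 (-0.35 ± 0.05). These values argue against such a shift for the 4 genes, while Cyp2a1, A1bg and Cux2 did not pass. The 95% bootstrap interval of the median of all 7, -0.346, ran from -1.01 to 0.0478. With so few genes it did not decide for the group. Of 7 male-biased genes 5 fell and none rose. The median of all 22 tested members, -0.298, differed from that of the hepatocyte secreted protein list by -0.101, with a 95% bootstrap interval from -0.297 to 0.121, so the fall was not shown to exceed that of other hepatocyte genes. A lower share of hepatocyte RNA stays open here as well (permutation p = 0.0659 across the markers of other cell types), although those markers showed no rise as a set. Among the list's regulators and targets of growth hormone, Igf1 fell (-0.47 ± 0.03) and Ghr did not pass (-0.26 ± 0.02). What lowered the list stays open. The labels do not give the sex of the rats.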
